A study of Mus musculus with 3 samples.

How the data were processed

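RNA from the esophagus, stomach and intestine primordia of ICR mouse embryos at E11.5 was labelled with Cy3 and measured on 1-colour Agilent mouse expression arrays, with 1 array per organ. The organ of each array was taken from its title and tissue label, because the labels' extraction text speaks of stomach for all 3 samples. Neither the number of embryos per sample nor any pooling is stated in the labels.

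The scanner files held spot intensity values read with Agilent Feature Extraction 10.5.1.1, per the file headers. The processed signal used here is an intensity after subtraction of the local background and correction of trends across the array, per the file headers, and it was not scaled between arrays. The median intensity of each spot and of its local background, also deposited, was used for an alternative background correction. A deposited table of log2 values for the same arrays had medians of −2.97 in esophagus, −3.17 in stomach and −3.47 in intestine. Set against each array's scanner values, these were log2 signals minus the array's 75th percentile, without centring of each probe, and after removal of 1 constant 99.8%, 99.9% and 99.9% of probes lay within 0.01 log2 units of the scanner value. They served as an alternative source of values. All 3 arrays lay on 1 slide and were read in 1 scan, so the place on the slide and the organ cannot be told apart.

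Each array held 45018 spots, of which 43379 were not controls. These carried 41174 different probes. Spots marked as outliers were left out (111 in esophagus, 70 in stomach, 77 in intestine), and no spot was saturated. The main value was log2 of the processed signal minus the array's 75th percentile over spots that were not controls, averaged over the spots of a probe, and 41112 probes had a value on every array. A probe counted as measured on an array when more of its spots than not were well above background. Probes were named by matching the array's accession column, without versions, to the transcripts in a RefSeq gene table of assembly GRCm38.p6, from which no position was used. In this way 24342 probes matched 1 symbol, covering 16998 genes, and 16770 probes with a value stayed without a symbol. Of the 5768 genes with 2 or more probes, each was represented by the probe with the highest mean over the 3 arrays.

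A gene entered a comparison when its probe was well above background on at least 1 of the 2 arrays. Where only 1 array measured it, the difference is a bound, taken against the higher of the dim array's lowest well-above-background signal and the dim probe's own signal, and is written as at least N-fold. That lowest signal was 8.17 in intestine, 5.85 in stomach and 7.03 in esophagus, against 75th percentiles of 1023, 334 and 393. Bounds can therefore read larger where intestine is the dim array, as for Csrp3, which was dim in both stomach and intestine. Genes at least 4-fold apart were counted, and genes at least 4-fold higher in 1 organ than in each of the others were counted separately. With 1 array per organ no test across genes was run. A gene was said to have probes that disagree when its measured probes differed in sign by more than 0.5 log2 units each way.

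The genes named were fixed by rule before the data were examined. For each comparison and direction these were the 10 genes with the largest difference measured on both arrays and the 3 with the largest bound, and for each organ the 5 with the largest difference above the higher of the other organs. Clone, predicted and unnamed transcripts were left out, and a few genes that met the rule are not named because they are withheld for evaluation. Members of 34 gene lists could also be named. The lists hold 432 genes, of which 414 had a named probe. They cover anterior gut regulators, stomach regulators, intestinal epithelium, stomach products, endoderm of the whole gut, hedgehog response, Wnt, BMP and TGF-beta, FGF and retinoid genes, Hox genes of groups 1 to 5, 6 to 8 and 9 to 13, smooth muscle, proliferation, reference genes, stress, hypoxia and sex genes. Marker lists cover enteric neural crest, neurons, trachea and lung, liver, pancreas, spleen, erythroid cells, endothelium, macrophages, heart, mesothelium, urogenital ridge, germ cells, skeletal muscle and cartilage. Each list's median difference was placed among the medians of 10000 random gene lists of the same size matched on mean signal in 20 bins. A list with fewer than 5 measured members got no percentile.

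Precision within an array was measured as the SD of log2 signal over the spots of a probe, for probes printed 10 times. The spread of a list median was the SD over random draws that moved each member by the SD between probes of 1 gene.

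The steps were tested on simulated data for the comparison of stomach and esophagus, over 13634 genes with noise of 0.1 log2 units. All 100 genes simulated with an 8-fold difference were counted as at least 4-fold apart, and 0 of 100 simulated with a 2-fold difference were. Among 13422 unchanged genes 0 were counted, and 44 of 1000 random lists (4.4%) fell outside the 2.5 to 97.5 percentile range. A first run with 200 random lists had 15 outside it (7.5%), and the number of lists was raised after that was seen. The simulated noise was smaller than the median SD between probes of the same gene, 0.25 log2 units for stomach against esophagus. The simulation therefore checks the steps of counting and ranking, and it does not measure the error of the differences between these arrays.

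The alternatives were normexp background correction (offset 50), quantile normalization, centring on the median of probes well above background on all 3 arrays, the deposited value table, no filter on dim probes, a filter asking for signal above background on every array compared, the mean of a gene's probes, and thresholds of 2-fold and 8-fold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, with R 4.3.3 and limma 3.58.1 for normexp and quantile normalization.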

Results

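Gene expression was measured in 3 organ primordia of the mouse gut, the esophagus, the stomach and the intestine, dissected from ICR embryos at E11.5. Each organ was represented by 1 array, so no difference given here has a replicate check, and the number of arrays limits the precision of every value. The share of spots well above background was 69.3% in esophagus, 67.9% in stomach and 74.0% in intestine. The 75th percentile of the processed signal was 393 in esophagus, 334 in stomach and 1023 in intestine. Relative to that percentile, the spike-in controls read 1.81 log2 units in esophagus, 1.81 in stomach and 0.91 in intestine, so the sample's own signal stood higher over the spike-ins on the intestine array. Spots of the same probe had a median SD of 0.086, 0.077 and 0.074 log2 units on the esophagus, stomach and intestine arrays. Probes of the same gene differed more, with a median SD of the difference of 0.25 log2 units for stomach against esophagus, 0.46 for intestine against esophagus and 0.31 for intestine against stomach.

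The comparison of stomach and esophagus asks which genes distinguish neighbouring foregut organs. Heart and striated muscle genes, anterior foregut regulators and tracheal and lung regulators were lower in stomach than in esophagus. Whether the esophagus primordium itself expressed the heart, striated muscle, tracheal and lung genes was not tested. Heart tissue in the dissection may account for the heart genes. Hox genes of groups 6 to 8, stomach regulators and several genes of intestinal epithelium were higher in stomach. Of 13750 genes, 94 were at least 4-fold higher in stomach (67 measured on both arrays and 27 bounds) and 218 were at least 4-fold lower (155 and 63). After normexp background correction, which shrinks the differences of dim genes, 28 were higher and 60 lower.

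Syt10, a synaptotagmin, was 204-fold higher in stomach than in esophagus, and Nepn and Nkx6-2 were at least 507-fold and at least 265-fold higher. Ihh, the gut hedgehog ligand, was 24.5-fold higher. Agr2 stood at 4.32 log2 units. Adra2a was 22.1-fold higher, Colec10 16.0-fold, Tspan8 14.8-fold and Cartpt 14.3-fold. Among the Hox genes of groups 6 to 8, 5 of 5 measured members were at least 2-fold higher, with Hoxa7 31.2-fold, Hoxb8 19.9-fold and Hoxb7 17.9-fold higher, and the list median was 4.16 log2 units (2.70 without the filter on dim probes). The other probe of Hoxb8 gave 2.60. Hox genes of groups 1 to 5 had a median of 0.33, inside the range of random lists, although Hoxb1 stood at 3.65. Those of groups 9 to 13 had 5 measured members with a median of 0.10 and went both ways.

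Among the stomach regulators, which include transcription factors of stomach mesenchyme and pylorus, 6 of 11 measured members were at least 2-fold higher in stomach and 2 were at least 2-fold lower, with a median of 1.13. Barx1, a homeobox gene of stomach mesenchyme, stood at 3.57 log2 units, Six2 at 2.28 and Isl1 at 1.77, and Tlx1 was at least 16.4-fold higher. Sfrp2 (−2.05) was lower. In the intestinal epithelium list 10 of 15 measured members were at least 2-fold higher in stomach than in esophagus, among them Vil1 (2.73) and Onecut2 (2.54), while Fabp1 (−1.68) was lower, and the median was 1.43. Genes of endoderm along the whole gut had a median of 0.38, with Krt18 (1.71) and Foxa3 (1.67) higher in stomach and Shh (−0.52) within 2-fold.

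The anterior gut list had 8 of 11 measured members at least 2-fold lower in stomach and a median of −2.36. Tbx1 (−4.54), Pax9 (−2.94) and Trp63 (−2.46), the regulator of basal squamous epithelium, were lower, whereas Sox2 (−0.47) was within 2-fold. Foxd1 was 135-fold lower in stomach. In the trachea and lung list (median −2.99) 6 of 9 members were at least 4-fold lower, with Wnt2 at −4.08 and Nkx2-1 and Sftpc, a surfactant protein gene, at bounds of −4.68 and −4.04, while Fgf10 (1.58) was higher. Nkx2-1 is also a member of the anterior gut list.

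In the heart list 12 of 14 members were at least 4-fold lower in stomach, and its median difference of −4.35 log2 units is a 20.4-fold difference. Mybpc3 was 144-fold lower, Myh6 95.7-fold, Cox6a2 94.5-fold, Tnnc1 82.2-fold, Myl4 59.7-fold, Myl7 57.4-fold and Tnnt2 55.5-fold lower. The striated muscle genes Csrp3, Sln and Ankrd1 were at least 163-fold, 99.5-fold and 58.8-fold lower. Myl3 was 58.0-fold lower by the probe used, but its other probe gave −0.57. In the skeletal muscle list 6 of 7 measured members were at least 4-fold lower, with a median of −2.71, including Myog (−5.20) and Ttn (−3.52), whose 8 probes ranged from −5.46 to −0.75. Smooth muscle genes had a median of −1.04, and 7 of 11 were at least 2-fold lower, among them Myh11 (−2.90), Cnn1 (−2.44) and Tagln (−1.93).

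The signalling lists had medians smaller in size than those of the heart, anterior gut, and trachea and lung lists. The Wnt list had a median of −0.58, with 5 of 25 genes at least 4-fold lower in stomach, including Rspo2 (−2.41), and 0 at least 2-fold higher. In the BMP and TGF-beta list (median −0.18) Inhba (−2.98) and Bmp3 (−2.84) were lower and Msx1 (1.38) and Fst (1.37) higher. The retinoid list had a median of −0.17, with Cyp26a1, which degrades retinoic acid, at −2.89. The hedgehog response list had a median of −0.25, with Boc (−1.44) lowest and Gli1 at 0.01. Enteric neural crest genes had a median of 0.90, and Ret (1.94) and Hand2 (1.81) were higher in stomach. Liver genes had a median of −1.37, with 8 of 12 measured members at least 2-fold lower in stomach, among them Alb (−2.03), but Ambp (2.20) was higher. The median difference of all genes was 0.147, and it was 0.235 after median centring, so small list medians in this comparison are to be read against that shift. Of the list medians given for this comparison, those of Hox groups 1 to 5 and 9 to 13 lay inside the central 95% of random lists matched on mean signal and the others lay outside it. After normexp correction the medians were −1.34 for anterior gut, 0.45 for intestinal epithelium, −1.08 for trachea and lung, −1.27 for skeletal muscle, −0.20 for Wnt, 0.44 for enteric neural crest and −0.41 for liver genes. With signal above background on both arrays the medians were 0.63 for stomach regulators, 1.95 for intestinal epithelium and −1.44 for trachea and lung genes, and without the filter on dim probes that of intestinal epithelium was 2.18.

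The comparison of intestine and esophagus sets the ends of the dissected gut against each other. Intestinal epithelial genes, hepatic genes and Hox genes of groups 6 to 13 were higher in intestine, and anterior gut, tracheal, cardiac and Wnt pathway genes were higher in esophagus. Here too, expression of the tracheal and cardiac genes by the esophagus primordium itself was not tested. Of 14471 genes, 253 were at least 4-fold higher in intestine (175 measured on both arrays and 78 bounds) and 536 were at least 4-fold lower (420 and 116). Under quantile normalization the split was even, with 370 genes higher and 369 lower, and after normexp correction 93 were higher and 214 lower.

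Syt10 was 944-fold higher in intestine than in esophagus, Mab21l2 160-fold and Nkx2-3, a homeobox gene of gut mesenchyme, 114-fold. Hand1 was at least 281-fold and Lgals2 at least 284-fold higher. In the intestinal epithelium list 11 of 15 measured members were at least 4-fold higher and the median was 3.52 log2 units. Cdx2, the regulator of intestinal identity, was at least 202-fold higher, Vil1, a microvillus protein gene, 74.0-fold and Fabp2, a fatty acid binding protein gene, 38.4-fold by the probe used, and Isx was at a bound of 7.38. The other probe of Fabp2 gave 2.52. Tdh was 62.1-fold and Colec10 51.3-fold higher. Saa2 and Saa3 were 51.5-fold and 36.7-fold higher, but these are members of a near-identical family whose probes cannot be told to separate them, so their values are uncertain. In the liver list 13 of 15 genes were at least 4-fold higher in intestine, including Ambp (4.27), Apoa1 (3.67) and Alb (3.35), and the median was 3.07. Prox1 (−2.34), a regulator of hepatoblasts, was lower.

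Hox genes of groups 6 to 8 had a median of 2.98, and 5 of 7 were at least 4-fold higher in intestine than in esophagus. Those of groups 9 to 13 had a median of 2.58, and 7 of 13 were at least 4-fold higher, among them Hoxc9 (31.9-fold) and, as bounds, Hoxa11 (6.85) and Hoxa10 (5.50). Hoxb9 (−0.83) was within 2-fold. Groups 1 to 5 had a median of 0.35, and 13 of 15 were within 2-fold.

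In the anterior gut list 9 of 11 genes were at least 4-fold lower in intestine than in esophagus and the median was −4.18. Trp63 (−7.22) and Pax9 (−6.25) were at bounds, though the other probe of Trp63 gave −2.73, and Sox2 stood at −3.64, while Krt14 (0.19) and Sox15 (0.53) were within 2-fold. Anxa8 was 185-fold and Foxd1 143-fold lower. Tbx5 was at least 663-fold lower by the probe used, and its other probe gave −3.31. Wnt2, a ligand of lung mesenchyme, was 89.6-fold lower. The trachea and lung list had a median of −4.12, and 6 of 9 members were at least 4-fold lower. That median was −2.10 after normexp correction, −1.85 with signal above background on both arrays, and −2.39 from the deposited value table, where Nkx2-1 stood at −2.39 against −5.81. In the heart list 12 of 14 genes were at least 4-fold lower, with a median of −4.21. Myh6 was 224-fold lower, Mybpc3 187-fold, Myl7 133-fold, Tnnt2 116-fold, Cox6a2 111-fold, Tnnc1 85.8-fold and Myl4 69.6-fold, and Csrp3 was at least 357-fold lower. Skeletal muscle genes had a median of −2.89, with Myog at −5.95, and smooth muscle genes a median of −1.07, with Myh11 at −3.08.

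Of 25 Wnt pathway genes, 11 were at least 4-fold lower in intestine than in esophagus and 2 at least 4-fold higher, and the median was −1.74. Rspo2 (−4.71), Wnt6 (−4.36) and Lef1 (−3.11) were lower, and Dkk2 (3.32) and Sfrp5 (2.06) were higher. In the retinoid list 9 of 15 genes were at least 2-fold lower, with a median of −1.08. Cyp26a1 (−3.95) and Aldh1a3 (−2.99) were lower, and Aldh1a2 (1.87) and Rdh10 (1.80) were higher. Stomach regulators had a median of −2.56, with Barx1 at −5.26. The BMP and TGF-beta list (median −0.18), the hedgehog response list (−0.14), the endoderm list (0.27) and the enteric neural crest list (−0.27) lay inside the range of random lists. Within them Inhba (−4.96), Osr1 (−4.50) and Foxa2 (−3.04) were lower in intestine and Ihh (4.08) higher. Hox groups 1 to 5 also lay inside that range, and the other list medians given for this comparison lay outside it. After normexp correction the medians were 2.02 for intestinal epithelium, 1.44 for Hox groups 6 to 8 and 0.99 for Hox groups 9 to 13.

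The comparison of intestine and stomach asks what distinguishes the organs on either side of the pylorus. Intestinal regulators, hepatic genes and Hox genes of groups 9 to 13 were higher in intestine, and stomach regulators and anterior gut genes were higher in stomach. Of 14392 genes, 198 were at least 4-fold higher in intestine (137 measured on both arrays and 61 bounds) and 178 were at least 4-fold lower (123 and 55). Under quantile normalization 229 were higher and 129 lower, and after normexp correction 51 were higher and 62 lower.

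Lgals2 was 102-fold higher in intestine than in stomach, Isx 74.9-fold, Cdx2 74.6-fold, Mab21l2 62.1-fold and Hand1 56.6-fold. In the intestinal epithelium list 7 of 16 genes were at least 4-fold higher, including Fabp1 (25.3-fold), Fabp2 (3.64) and Vil1 (3.48), while Hnf4a (1.07, with 3 probes from −0.44 to 1.07) and Hnf4g (0.03) differed less. At least 2-fold lower were 2 genes, Gata4 (−1.24) and, as a bound, Cdx1, which was not well above background in intestine. Cdx1 was near the floor in stomach too, at −5.57 log2 units relative to the 75th percentile. Its bound therefore rests on a dim signal and on the lower relative floor of the intestine array. The list median was 1.43. Fabp1 was lower in stomach than in esophagus (−1.68), as were 9 of 12 measured liver genes, whereas Vil1 and Fabp2 were higher in stomach. Whether Fabp1 shares the source of the hepatic genes was not tested. In the liver list 13 of 15 genes were at least 4-fold higher in intestine and the median was 3.89. Ahsg was 45.3-fold, Alb 41.7-fold and Fgg, a fibrinogen gene, 25.1-fold higher, and Prox1 (−0.55) and Hhex (1.09) were not among the 13.

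Hox genes of groups 9 to 13 had a median of 3.04, and 7 of 13 were at least 4-fold higher in intestine than in stomach. Hoxc9 was at least 130-fold, Hoxa11 at least 118-fold and Hoxa10 at least 46.3-fold higher, and Hoxb9 (−2.63) was lower. Groups 6 to 8 went both ways, with Hoxc8 (a bound of 4.37) higher and Hoxb8 (−2.37) and Hoxa7 (−1.98) lower, and a median of −0.47. Groups 1 to 5 had a median of −0.31, and Hoxb1 stood at −3.25.

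Barx1 was 454-fold lower in intestine than in stomach. Of 11 stomach regulators 6 were at least 4-fold lower, among them Six2 (34.9-fold), Nkx2-5 (−3.95) and Pitx1 (−3.87), and the median was −2.77. Lor, a gene of the cornified envelope, was 36.2-fold lower, Hs3st3b1 32.7-fold, Kctd8 31.5-fold, Prap1 30.7-fold, Anxa8 25.9-fold, Dmrt2 24.0-fold, Nkx6-2 21.2-fold and Pappa 20.7-fold. Sox21 was at least 71.1-fold, Lhx9 at least 67.1-fold and Sim2 at least 51.6-fold lower. The other probe of Lhx9 gave −2.52 and that of Pappa −1.999. The anterior gut list had a median of −2.24, with Sox2 at −3.17 and Trp63 at a bound of −4.76. The trachea and lung list had a median of −1.32, with Tbx5 at a bound of −5.41. Heart genes had a median of −0.51 and went both ways, with Myh7 (−2.12) lower and Myl3 (2.05) higher, but the other probe of Myl3 gave 0.23 and Myl3 lay at −0.07 after normexp correction. Skeletal muscle genes (−0.27) and smooth muscle genes (0.06) had medians near 0.

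Wnt pathway genes had a median of −0.63, with Sp5 (−3.26), Wnt11 (−2.42) and Lgr5 (−2.17) lower in intestine than in stomach and Dkk2 (3.14) higher. Retinoid genes had a median of −0.69, with Aldh1a1 (2.28) and Rdh10 (2.07) higher and Aldh1a3 (−1.67) lower. The BMP and TGF-beta list had a median of 0.08, with Bmp4 (1.56) higher and Sostdc1 (−2.33) lower, and the hedgehog response list a median of −0.03, with Osr1 (−3.44) and Ptch1 (−1.62) lower. Endoderm genes had a median of −0.42, with Foxa2 (−2.68) and Krt18 (−1.06) lower. In the enteric neural crest list 10 of 11 genes had negative values, among them Erbb3 (−2.28) and Ret (−1.26), and the median was −0.78. The medians of Hox groups 6 to 8, skeletal muscle, smooth muscle, BMP and TGF-beta and hedgehog response genes lay inside the range of random lists, and the others given for this comparison lay outside it. After normexp correction the medians were 0.61 for intestinal epithelium, 0.88 for Hox groups 9 to 13, 2.19 for liver and −1.04 for heart genes. The anterior gut median was −1.23 with signal above background on both arrays, and the trachea and lung median −0.81 with the mean of a gene's probes.

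**Figure D1:**
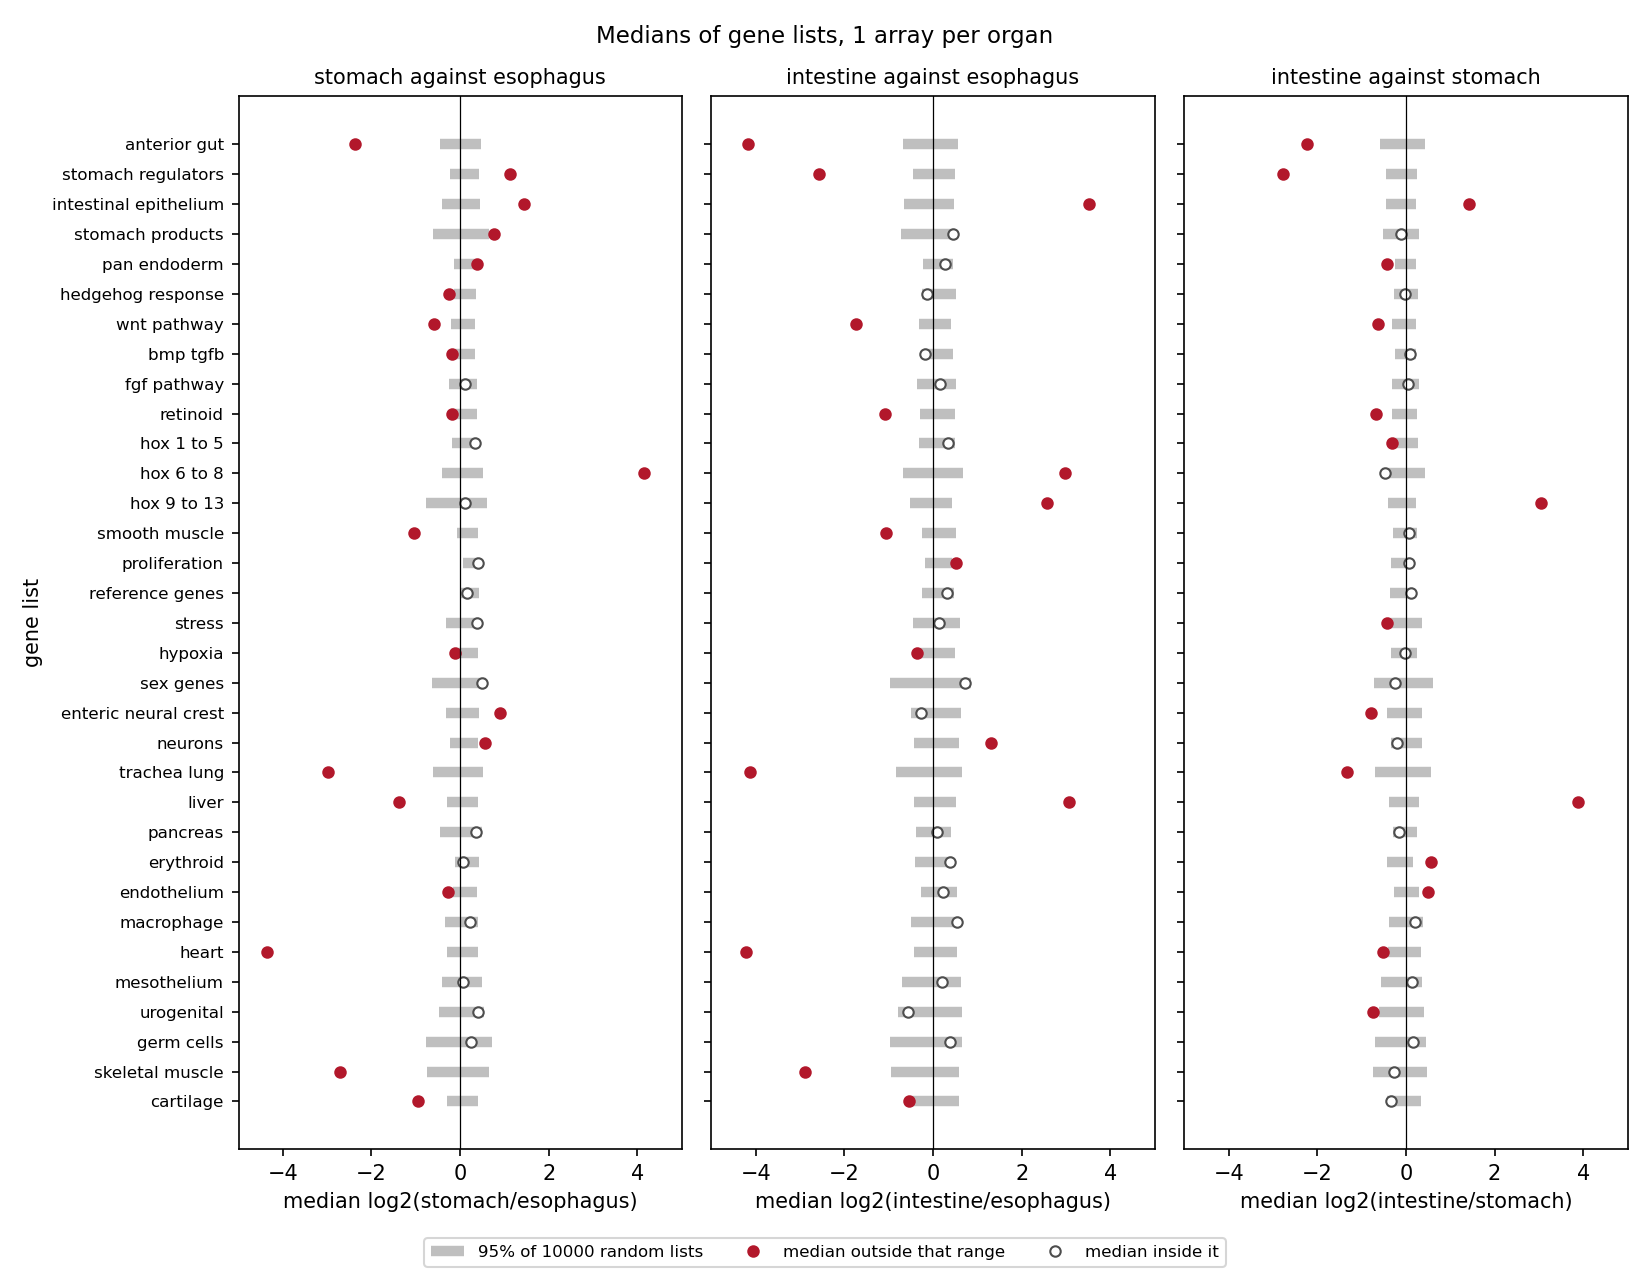
Median log2 difference of each gene list (vertical axis) in the 3 comparisons, 1 array per organ, with grey bars for the central 95% of 10000 random lists matched on mean signal. Heart genes lie at −4.35 and −4.21 in the comparisons with esophagus and at −0.51 between intestine and stomach.

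Genes at least 4-fold higher in 1 organ than in both others numbered 171 of 13301 in esophagus, 33 of 13384 in stomach and 140 of 14289 in intestine. In esophagus they included 12 heart, 6 skeletal muscle, 6 trachea and lung and 6 anterior gut genes, and Csrp3 (at least 163-fold), Mybpc3 (144-fold), Foxd1 (135-fold), Sln (at least 99.5-fold) and Myh6 (95.7-fold) had the highest values. These counts cover members of the gene lists only, and muscle genes outside the lists, such as Csrp3, Mybpc3 and Sln, come on top of them. In stomach they were led by Nkx6-2 (21.2-fold), Tlx1 (at least 16.4-fold), Barx1 (11.8-fold), Atoh1 (at least 10.9-fold) and Sim2 (10.9-fold), and included 3 stomach regulators. Of these regulators, Tlx1 is also a member of the splenic list. In intestine they included 13 liver, 7 intestinal epithelium and 7 Hox genes of groups 9 to 13, and were led by Hoxa11 (at least 115-fold), Lgals2 (102-fold), Isx (74.9-fold), Cdx2 (74.6-fold) and Mab21l2 (62.1-fold). After normexp correction the numbers were 51 in esophagus, 7 in stomach and 40 in intestine.

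**Figure D2:**
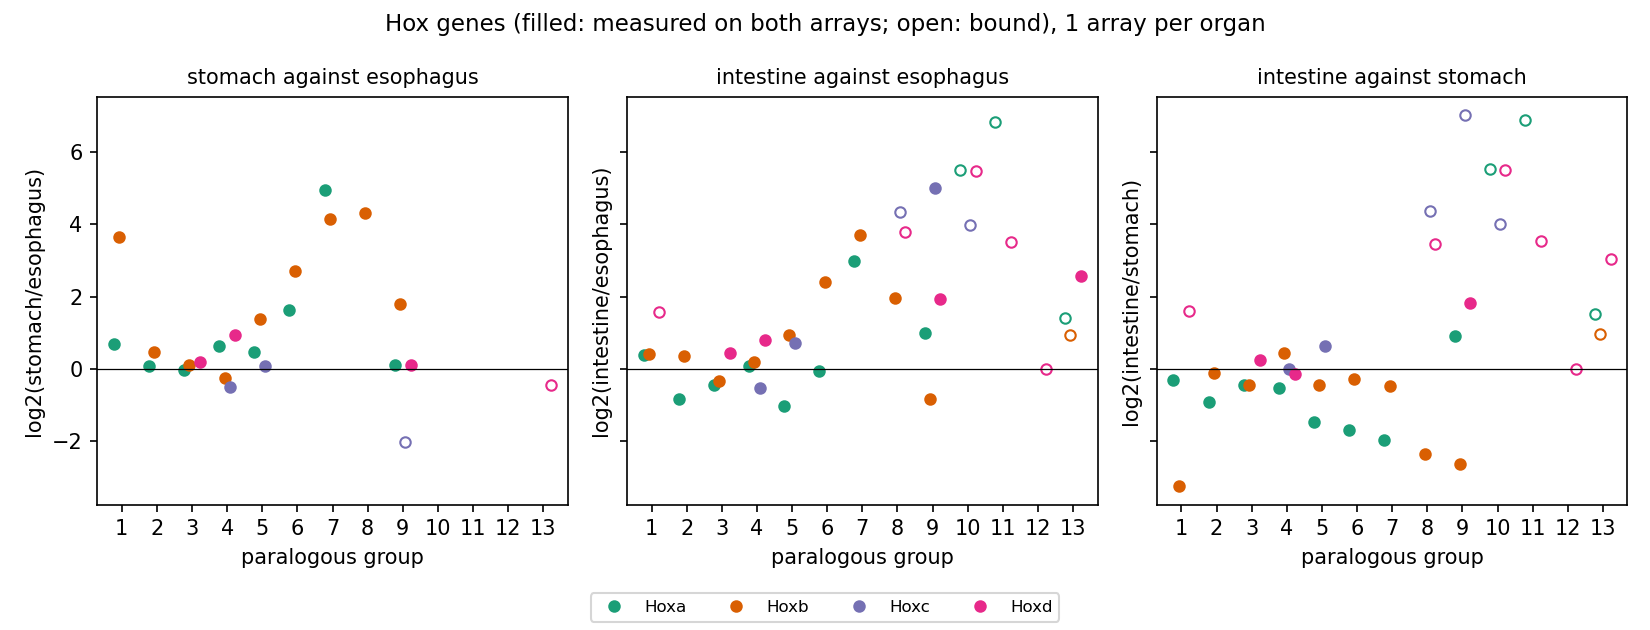
Log2 differences of the measured Hox genes in the 3 comparisons, by Hox group, 1 array per organ. Filled points are genes measured on both arrays and open points are bounds. Hoxa7 stands at 4.96 in stomach against esophagus, and Hoxa11 at a bound of 6.88 in intestine against stomach.

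**Figure D3:**
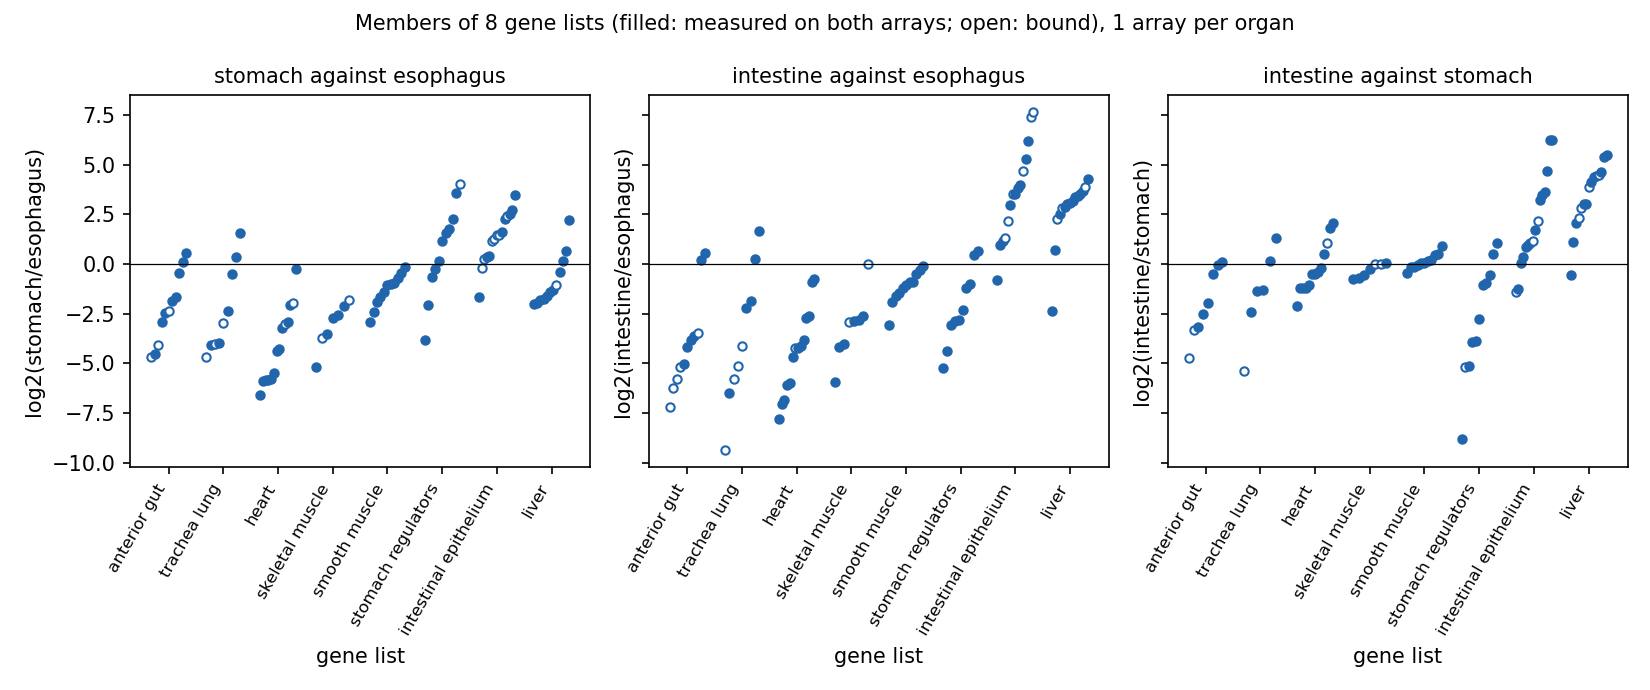
Log2 differences of the members of 8 gene lists in the 3 comparisons, 1 array per organ, with filled points for genes measured on both arrays and open points for bounds. Heart and skeletal muscle genes lie below 0 in both comparisons with esophagus, apart from 1 skeletal muscle bound at 0.

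Across 14517 genes, the arrays of stomach and esophagus had a Pearson r of 0.967 (Spearman's rho 0.975), those of intestine and esophagus 0.939 (0.951) and those of intestine and stomach 0.966 (0.974). These correlations are across genes, which are not independent replicates. Over all comparisons, 52 of 99 list medians lay outside the central 95% of random lists, where 4.95 are to be had by chance if lists were independent. Lists share genes and their members vary together, so this describes these arrays and not the organs at large. Each array enters more than 1 comparison, so whatever is particular to an array appears in all of them. The sizes of single-gene differences depend on the background correction: after normexp, 243 of 293 values of named genes and of list members at least 4-fold apart moved toward 0 by more than the SD between probes, 1 changed sign and 49 stayed within it. Probes of 1 gene disagreed in sign for 98 genes in stomach against esophagus, 553 in intestine against esophagus and 259 in intestine against stomach.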

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

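No test of an explanation was run for the results in this part, and the counts were chosen after the naming of probes was seen. Probes without a gene symbol enter no comparison of genes. Of those well above background, 91 of 8856 (1.03%) were at least 4-fold higher in esophagus than in both other organs, 21 of 8286 (0.253%) in stomach and 26 of 9597 (0.271%) in intestine. Among named genes the shares were 1.29% in esophagus, 0.247% in stomach and 0.980% in intestine. The highest such probe was A_51_P210835 in esophagus, at a bound of 5.71 log2 units, A_52_P395492 in stomach, at a bound of 4.92, and A_51_P365516 in intestine, at 4.996. These results stand out as signal in data that the comparisons of named genes do not use. Which transcripts these probes measure is not known here, and no explanation was tested.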

How the results depend on the processing

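Normexp on median signals was chosen after the columns of the files were seen, in place of the planned normexp on mean signals, which was not run because the mean signal column is absent. The other settings were planned. No paired analysis was possible because each organ has 1 array. Median centring moved 0 of the counts, correlations, list medians and named genes by more than their margin. The deposited value table moved the trachea and lung median of intestine against esophagus to −2.39, the value there of Nkx2-1, which stood at −5.81 in the scanner files. Of the list medians outside the random range, taken over all settings, 309 kept within their spread, 53 moved and 1 changed sign. Of 293 values of named genes and of list members at least 4-fold apart, normexp moved 243, each toward 0, and changed the sign of 1. Leaving out the filter on dim probes moved 53, each away from 0, the mean of a gene's probes moved 30 toward 0 and 7 away, quantile normalization 14 toward 0 and 11 away, and the deposited values moved 2 toward 0. Signal over background limits genes near the floor. The median difference of all genes for intestine against esophagus was 0.104, and it was 0.198 under quantile normalization and 0.246 under median centring.

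Normexp with its offset of 50 shrinks differences of dim genes by construction. Counts of genes at least 4-fold higher and lower became 28 and 60 for stomach against esophagus, 93 and 214 for intestine against esophagus, and 51 and 62 for intestine against stomach. Genes above both other organs became 51 in esophagus, 7 in stomach and 40 in intestine. For stomach against esophagus the medians became −1.34 (anterior gut), 0.45 (intestinal epithelium), 0.30 (stomach products), −0.20 (Wnt), 2.92 (Hox groups 6 to 8) and 0.44 (enteric neural crest). They became −1.08 for trachea and lung, −0.41 for liver, −3.17 for heart, −1.27 for skeletal muscle and −0.23 for cartilage. For intestine against esophagus they became −3.05 (anterior gut), −1.98 (stomach regulators), 2.02 (intestinal epithelium), −1.26 (Wnt), 1.44 (Hox groups 6 to 8) and 0.99 (Hox groups 9 to 13). Trachea and lung became −2.10, liver 2.32, heart −3.46 and skeletal muscle −2.05. For intestine against stomach they became −1.68 (anterior gut), 0.61 (intestinal epithelium), 0.88 (Hox groups 9 to 13), 2.19 (liver), −1.04 (heart) and −1.10 (urogenital). The sign changed for the erythroid median (−0.0267) and for Myl3 (−0.0723), both for intestine against stomach. The heart and urogenital medians of this comparison lay farther from 0 than before, and the cause was not tested.

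Quantile normalization moved the intestine against esophagus medians of Wnt genes to −1.24 and of skeletal muscle to −2.42, and the cause was not tested. Its higher and lower counts stayed within 1.5 times the main ones, though the balance shifted to 370 against 369 for intestine against esophagus.

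Without a filter on dim probes more genes enter and bounds become measured differences. Counts became 184 higher and 350 lower for stomach against esophagus, 396 higher for intestine against esophagus, and 306 higher and 289 lower for intestine against stomach. The correlation of intestine and esophagus became 0.960. Medians for stomach against esophagus became 2.18 (intestinal epithelium), 0.40 (stomach products), 2.70 (Hox groups 6 to 8) and −3.96 (trachea and lung). For intestine against stomach they became −1.18 (anterior gut) and 3.60 (Hox groups 9 to 13).

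With signal above background asked of every array compared, fewer genes enter and no bound remains, and genes or lists left without enough measured members gave no value. Genes above both other organs became 110.0 in esophagus, 19 in stomach and 78 in intestine. Medians for stomach against esophagus became −1.76 (anterior gut), 0.63 (stomach regulators), 1.95 (intestinal epithelium), −1.44 (trachea and lung) and −4.95 (heart). For intestine against esophagus they became 2.41 (Hox groups 6 to 8), 1.93 (Hox groups 9 to 13), −1.85 (trachea and lung) and −3.45 (skeletal muscle). For intestine against stomach they became −1.23 (anterior gut) and −1.91 (stomach regulators).

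The mean of a gene's probes gave medians for stomach against esophagus of −2.03 (anterior gut), 3.46 (Hox groups 6 to 8), 0.49 (enteric neural crest) and −3.81 (heart). For intestine against stomach it gave −0.81 (trachea and lung) and 3.44 (liver). The cause was not tested.

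At 2-fold the counts higher and lower were 569 and 786 for stomach against esophagus, 1215 and 1669 for intestine against esophagus, and 686 and 1033 for intestine against stomach. Above both others they were 584, 148 and 478 in esophagus, stomach and intestine. At 8-fold they were 36 and 78, 99 and 187, and 81 and 61 in the same order of comparisons, and 65, 13 and 54 above both others. Among probes below the array's median signal the SD between spots was 0.21 in esophagus, 0.23 in stomach and 0.19 in intestine, and the cause was not tested.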

Other observations

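The test of where the outer organs lie relative to stomach was chosen after the related result was seen, and so were the margins by which a value had to pass its limit. Several gene groups outside the main comparisons differed between the arrays. Of 11 neuronal genes, 6 were at least 2-fold higher in intestine than in esophagus (median 1.31) and 5 were at least 2-fold higher in stomach (median 0.56), with Isl2 at 2.94 and 3.47, and between intestine and stomach the median was −0.19. Proliferation genes had medians of 0.41 in stomach and 0.53 in intestine against esophagus and 0.07 between intestine and stomach, with Cdk1 (1.49) and Pcna (1.44), a replication clamp gene, highest in intestine against esophagus. In the FGF list Etv4, a target of FGF signalling, stood at 1.74 in stomach and 2.01 in intestine against esophagus, while the medians were 0.10, 0.16 and 0.05 in the order stomach against esophagus, intestine against esophagus and intestine against stomach. In that order, stomach products had medians of 0.76, 0.45 and −0.12, with Tff1, a trefoil factor gene, at least 2.61 log2 units higher in stomach than in esophagus and Cldn18 at a bound of −3.98 in intestine against stomach. The first of these medians was 0.30 after normexp correction and 0.40 without the filter on dim probes. Cblif and Pgc, products of mature stomach glands, were not well above background on any array. Pancreatic genes had medians of 0.37, 0.09 and −0.15, and went both ways. Pdx1 was at a bound of 2.09 in stomach against esophagus, Cpa1, a digestive enzyme gene, stood at 4.10 in intestine against stomach, and Nkx6-1 (−2.88) and Mnx1 (−3.27) were lower in intestine than in stomach. The splenic list had too few measured members for a median, and Tlx1 was at a bound of −5.20 in intestine against stomach. Of its 4 measured members, 3 were at least 2-fold higher in stomach than in esophagus. Against stomach, 2 of 4 were at least 4-fold lower in intestine. Splenic tissue in the stomach dissection was not tested.

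Other tissue groups are given in the same order of comparisons. Endothelial genes had medians of −0.28, 0.22 and 0.49, with Tek at −1.60 in stomach against esophagus. Macrophage genes had medians of 0.23, 0.55 and 0.20. Erythroid genes had medians of 0.06, 0.39 and 0.56, and the last changed sign under normexp correction (−0.03). In that comparison the globin gene Hbb-y stood at −0.73, though globin genes are near-identical to each other and their values are uncertain. Mesothelial genes had medians of 0.07, 0.20 and 0.14, with Tbx18 at −4.48 in stomach against esophagus and Msln at −2.87 in intestine against stomach. Urogenital genes had medians of 0.41, −0.55 and −0.74, with Osr1 at −3.44 in the last. Germ cell genes had medians of 0.24, 0.39 and 0.16. Cartilage genes had medians of −0.95 (−0.23 after normexp correction), −0.53 and −0.35, with Hapln1 (−1.89) and Sox9 (−1.07) lower in stomach than in esophagus and Col9a1 (3.23) higher in intestine than in stomach. Reference genes had medians of 0.16, 0.31 and 0.12, although Actb stood at −1.98 in intestine against esophagus and −1.77 in intestine against stomach. Stress genes had medians of 0.39, 0.14 and −0.42, and hypoxia genes −0.12, −0.36 and −0.02. Sex genes had medians of 0.50, 0.73 and −0.26, with Xist at −1.50 and −2.23 in stomach and intestine against esophagus. This list joins Xist with Y-linked genes, which differ by sex in opposite directions, so its median is hard to read. Against esophagus, 4 of 5 members were higher in stomach and 3 of 5 in intestine. A difference between the arrays in the sex of the embryos was not tested. Among the lists of this part, the medians outside the central 95% of random lists were those of stomach products, neurons, endothelium, cartilage and hypoxia in stomach against esophagus, of neurons, proliferation, cartilage and hypoxia in intestine against esophagus, and of erythroid, endothelial, urogenital and stress genes in intestine against stomach. Medians and means had opposite signs in stomach against esophagus for Hox groups 9 to 13, erythroid and mesothelial genes, and in intestine against esophagus for FGF and mesothelial genes. The same held in intestine against stomach for BMP and TGF-beta, FGF, Hox groups 6 to 8, reference, hypoxia, mesothelial and cartilage genes, all inside the range of random lists.

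Heart and skeletal muscle genes were higher in the esophagus array than in the others. The heart median for esophagus over stomach was at least 3.17 log2 units under quantile normalization, median centring and normexp, with a spread of 0.11. Quantile normalization and median centring could not have removed it, because they left the all-gene median for stomach over esophagus at 0.133 and 0.235. Random lists of like brightness lay between −0.10 and 0.29 for stomach over esophagus under normexp, where the heart median was −3.17. That argues against a scaling shared by genes of like brightness. Heart tissue in the dissection may account for the heart genes, and a separate cardiac list, written before its values were seen, had a median of 1.28 (spread 0.25) above the higher of the others, between the limits of 1 and 2 set for it. In it 5 of 10 measured genes were at least 2-fold higher, among them Hspb7 (3.06), and Popdc2 (−1.41) was lower. Skeletal muscle precursors are open on the same footing, with a median of 1.22 (spread 0.23) for a separate list and 6 of 12 genes at least 2-fold higher, such as Cav3 (3.54), and expression by the esophagus primordium itself was not tested. The source of the tracheal and lung genes that were higher in the esophagus array was not tested either.

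Hepatic genes were higher in the intestine array than in the stomach array. The test of array brightness or scaling set in advance does not decide. The liver median was lowest under normexp, at 2.19 (spread 0.22), and passed its limit of 2 by less than the spread. It was 4.05 and 3.94 under quantile normalization and median centring. Random lists of like brightness were brought in after that was seen. They lay between −0.67 and 0.05 under normexp, and their ranges ended at 0.42 and 0.35 under quantile normalization and median centring. The liver median lay above each range, which argues against a scaling shared by genes of like brightness. Hepatic tissue in the dissection may be the source, and a separate hepatic list had a median of 1.22 (spread 0.20), with 6 of 10 genes at least 2-fold higher, such as Rbp4 (3.33), and Hp (−0.77) within 2-fold. Transcription of some of these genes by gut endoderm may be another, and a list of clotting factor genes had a median of 0.45, below its limit of 0.5 by less than its spread of 0.28, with 5 of 11 genes at least 2-fold higher, such as Kng1 (3.89) and F12 (3.21), F9 (−1.35) and Hrg (−1.13) lower, and Serpinc1 (−1.78) with probes of opposite sign. Both stay open and cannot be told apart from these arrays, since neither list median passed its limit by more than its spread.

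More genes differed at least 4-fold between intestine and esophagus than in the other comparisons. Array brightness or scaling is argued against, since under quantile normalization with signal on both arrays this comparison had 2.30 times the genes of the next (536 against 233). Distance along the gut may account for it, and stomach lay at a median position of 0.320 between esophagus at 0 and intestine at 1 in the 164 genes higher in intestine and at 0.487 in the 398 genes higher in esophagus, counting genes measured on both arrays and leaving out the heart, skeletal muscle, liver, pancreas and trachea and lung lists. Choosing genes by the outer organs places the stomach array between them even without any order, so this does not decide. With the same genes left out, on the scale from 1 outer organ to stomach at 1, the other outer organ had a lowest median position of 0.729, between the limits of 0.5 and 0.8, and 1.06, 0.882 and 0.903 in the other groups of genes, which leaves distance along the gut open. Probes of 1 gene also differed most between intestine and esophagus, with a median SD of 0.46 log2 units against 0.25 and 0.31 in the other comparisons. A difference in RNA or labelling between the arrays was not tested.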
